A study of Mus musculus with 36 samples.

How the data were processed

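RNA was measured in 36 libraries of mouse embryonic stem cells and embryoid bodies, 3 libraries for each of 12 groups. The groups are 2 genotypes, control AB2.2 cells and AB2.2 cells lacking LncCPR, each at days 0, 3, 5, 8, 10 and 12 of differentiation. Per the labels, the deletion used Cas9 with a pair of guide constructs that flank the gene, cells were sorted singly, and lines carrying the deletion were expanded. The number of lines behind the 18 knockout libraries is not stated. Total RNA was taken with RNeasy columns from undifferentiated cells and from whole embryoid bodies, and libraries were made with ScriptSeq Complete Gold, a kit for total RNA that removes ribosomal RNA. Such libraries also hold long noncoding and unspliced RNA. The labels name HiSeq3000 in the protocol and Hiseq 2000 in the design text, so the instrument is uncertain.

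The deposited values are FPKM, a count of fragments scaled by transcript length and library total, made by the authors. They come as 6 tables, 1 per day, of 37561 gene entries and 6 libraries each. The submitters' processing notes name TopHat, a spliced aligner, Cufflinks, which estimates transcript abundance, and the mouse build mm9, with no versions, settings or annotation. It is not stated whether the libraries of a table were scaled to each other, or whether the 6 tables were normalized together. FPKM divides by the library total, so a transcript that takes a large share lowers all other values of that library. The ribosomal RNA of mitochondria is such a case: mt-Rnr2 was listed at 0 in 32 libraries and reached 69239 FPKM in the other 4. Cufflinks can also list 0 for a gene that is abundant, and 17 values in 13 genes were 0 where the other libraries of that day all held 5 FPKM or more.

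FPKM carries no read count, so the absolute depth is unknown and no interval or limit of detection that needs counts is given. Relative depth was read from genes seen in a minority of libraries, taken to hold mostly a single fragment each. It is the inverse of the most common ratio of their FPKM to that in control replicate 1 at day 0. Relative depth ran from 0.562 to 1.83 times that of this library, a 3.25-fold range. The lowest value, knockout replicate 1 at day 8, rests on 9 of 60 genes compared. The values of a library summed to between 294740 and 403675 FPKM, and 11248 to 13183 genes lay above 1 FPKM. The 10 most abundant genes held 11.3% to 30.3% of the sum, and over 20% in 8 libraries. Pairs of replicates correlated across genes at r from 0.969 to 0.992 on the log2 scale, genes not being independent replicates.

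Each day was tested within its own table. Genes with a mean of 1 FPKM or more over the day's 6 libraries were put on the scale log2(FPKM + 1) and tested for knockout minus control with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of variance on abundance), a two-sided moderated test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. An exact permutation test of 3 against 3 cannot go below 0.1, so single genes rest on this model, which pools the spread over genes. A limma F test over all 36 libraries asked whether the knockout effect differed between days, and the 6 lists of genes were intersected. Levels were not tested across days. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

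Before the data were examined, 31 gene lists of 592 genes were fixed for the stages and cell types an embryoid body can hold, for signalling pathways, cell cycle, stress, imprinting, sex chromosomes and RNA quality; 12 of the 592 matched no gene entry. Camera tested each list of 3 or more measured genes against the other genes with a preset correlation of 0.01 between genes, adjusted over 162 combinations of list and day. Of these, 72 passed the threshold with the preset correlation and 0 passed with an estimated correlation, where the lowest adjusted p of the 72 was 0.186. The estimate rests on 4 residual degrees of freedom, and both values are given. In 35 combinations the list's median, mean and direction of the test did not share a sign, 3 of them among the 72. Counts of genes are given over all genes tested and adjusted over the list alone.

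The genes named were set by a rule fixed at the same time: at each day the 5 highest and 5 lowest fold changes past the threshold with no overlap between the groups' libraries and 5 FPKM or more in the higher group; up to 4 members of each list with 2 or more members past the threshold, and of the lists for pluripotency, primitive streak, cardiac mesoderm and cardiomyocytes at any number; a panel of 19 marker genes; the genes past the threshold at all days; and the 10 genes that differed most between days. Genes outside the rule are said to be so. Chromosomes and neighbours were looked up in the GRCm38 annotation by Ensembl gene identifier, which matched 32616 of the 37561 entries. The tables carry no positions and the authors aligned to mm9, so no coordinates are given.

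The test was tried on simulated data drawn from each day's control means and the spread of each gene within the groups, with 200 genes changed by set sizes. At day 0, a log2 change of 1 was recovered in 92.5% of genes, and at day 3 in 34.3%, with 62.7% to 71.6% at the other days. A log2 change of 0.5 was recovered in 0% to 41.8% of genes, so small changes are missed, most often at day 3. At day 0, 13 of 167 calls were false, and at day 8, 4 of 111. The simulated noise was independent between genes and held no scaling error of whole libraries. These shares may therefore not carry over to the real data. The alternatives tried were a pseudocount of 0.1, no filter or a filter at 5 FPKM, median-ratio rescaling, quantile normalization, a block for the replicate number, 1 fit for all 36 libraries, robust eBayes, and leaving out each library or day in turn. Zeros set to missing, leaving out genes on chromosomes 1, 6 and 8, and leaving out the 8 libraries dominated by 10 genes were added after the data had been seen. Other value columns do not occur in the tables, and reads, isoforms and splicing were not analysed here.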

Results

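The study follows mouse embryonic stem cells as they leave pluripotency, pass through early mesoderm and form beating heart muscle, and asks what changes when the long noncoding RNA LncCPR is deleted. AB2.2 is a mouse embryonic stem cell line. Cells were kept undifferentiated (day 0), or the cytokine LIF was withdrawn and they were grown as embryoid bodies. These hanging-drop aggregates, in which the 3 germ layers form, were collected whole at days 3, 5, 8, 10 and 12. RNA sequencing covered control AB2.2 cells and LncCPR-knockout cells with 3 libraries per group and day, 36 libraries in 12 groups. The values are deposited FPKM of 37561 genes, and 11976 to 13089 genes per day had a mean of 1 FPKM or more and were tested. The FPKM of a library summed to between 294740 and 403675. Relative depth spanned a 3.25-fold range, and absolute depth is unknown. Values below are the mean ± SD of 3 libraries, fold changes are log2 of knockout over control on FPKM + 1, and SE is their standard error. A number in brackets after a gene name is its log2 fold change. Unless said otherwise, the 3 control and 3 knockout libraries of a gene called higher or lower did not overlap, which is the lowest exact p of 0.1 that 3 against 3 allows.

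No entry of the tables is named LncCPR, so its own level could not be read. The gene that separated the lines most sharply at the 6 days was 4930500J02Rik (ENSMUSG00000086454.1), an unstudied RIKEN transcript on chromosome 2 in GRCm38. It was listed at 5.66 to 49.5 FPKM in 18 of 18 control libraries, at 0 in 16 of 18 knockout libraries, and at no more than 0.280 FPKM in the other 2. At day 0 its level was 48.1 ± 1.39 FPKM in control and 0 ± 0 FPKM in knockout (adjusted p = 3.41e-08), and at day 5 22.0 ± 2.92 FPKM in control and 0.0932 ± 0.161 FPKM in knockout (log2 fold change -4.40, SE 0.15, adjusted p = 8.74e-08). Expressed genes within 500 kb of it, 11 or 12 per day, had median log2 fold changes between 0.026 and 0.33. At days 0, 5, 8 and 10, 1 of them passed the threshold as lower, and 0, 2, 1 and 4 as higher. Over all genes tested, 14.5%, 10.4%, 3.28% and 20.2% passed at those days.

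Of 10739 genes tested at the 6 days, 3 passed the threshold in the same direction each time, where independent lists would give 1.79e-05 higher and 1.15e-07 lower. They were 4930500J02Rik, the maternally expressed imprinted RNA H19, lower, and the Y-linked RNA helicase gene Ddx3y, higher. H19 went from 6.88 ± 0.705 FPKM in control and 1.38 ± 0.585 FPKM in knockout at day 0 to 216 ± 8.03 FPKM in control and 18.6 ± 6.5 FPKM in knockout at day 10 (log2 fold change -3.52, SE 0.20, adjusted p = 4.82e-07). Ddx3y lay at 16.3 ± 0.711 FPKM in control and 51.8 ± 0.712 FPKM in knockout at day 0 (log2 fold change 1.61, SE 0.058, adjusted p = 2.08e-05), and its log2 fold change was 1.62 at day 3, 0.77 at day 5, 0.81 at day 8, 0.84 at day 10 and 0.70 at day 12. Its day 8 call ended in 5 of the 6 ways to leave out 1 library. The genes Uty and Eif2s3y, also on the Y chromosome, were higher as well at day 0 (log2 fold changes 0.88 and 0.47). The Y-linked list of 3 genes was called higher at each day, with adjusted p from 1.22e-05 at day 3 to 0.0278 at day 10, and adjusted p = 0.290 and 0.400 at these days with an estimated correlation.

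Whole chromosomes also differed between the lines. Genes on chromosomes 6 and 8 lay lower in the knockout at days 0 and 3, and genes on chromosome 1 lay lower at days 5, 8, 10 and 12 (GRCm38 chromosomes). In these 8 combinations the chromosome's median log2 fold change was 0.24 to 0.30 below that of the other chromosomes, and 82.8% to 88.1% of its genes lay below the others' median. The 112 other combinations, without the Y chromosome, had shifts from -0.087 to 0.070. In the 8 combinations the 3 knockout libraries lay apart from the 3 control libraries, and camera adjusted p was at most 1.04e-11, and adjusted p = 0.173 or higher with an estimated correlation. Lying apart does not mark out these 8. Many other combinations did so too, such as chromosome 10 at day 0 with a shift of 0.0018. At day 0, 189 and 212 of the 979 genes lower in the knockout were on chromosomes 6 and 8. At days 5, 8, 10 and 12, 73, 37, 119 and 84 genes lower in the knockout were on chromosome 1. Within the control line, the chromosome 8 median fell by 0.24 from day 3 to day 5 relative to the others, chromosome 6 by 0.20, chromosome 1 moved up by 0.21, and the few expressed genes of the Y chromosome by 0.70. Within the knockout line these changes were -0.037, 0.055, 0.028 and -0.080. Single genes on these 3 chromosomes with small fold changes cannot be read as effects of LncCPR alone.

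**Figure D1:**
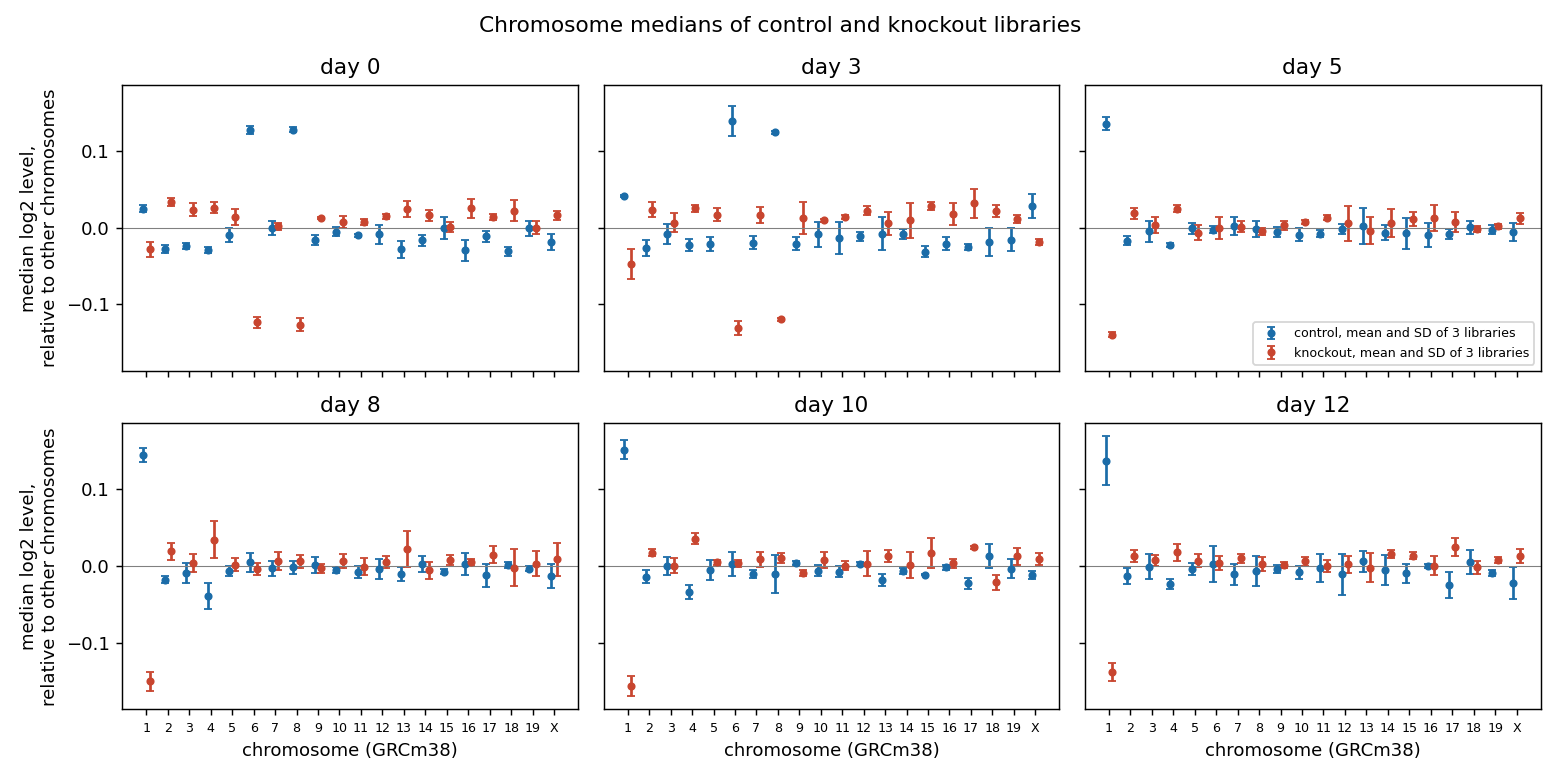
Median of the genes of each chromosome relative to the other chromosomes, per day and line, mean and SD of 3 libraries. Each gene was first centred on its mean over the day's 6 libraries, so the lines mirror each other by construction. Chromosome 6 at day 0, for example, has 0.127 in control and -0.124 in knockout. Only the gap between the lines can be read, not which line moved. The shift between the lines at day 0 is -0.25 for chromosome 6 and -0.26 for chromosome 8, and at day 10 it is -0.30 for chromosome 1.

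The control line shows the stages of heart formation in order. Pou5f1, the core pluripotency factor, was listed at 505 ± 13.7 FPKM at day 0, 158 ± 16.9 at day 5 and 15.8 ± 4.42 at day 10. T, which marks the primitive streak, peaked at day 5 with 64.2 ± 15.6 FPKM, as did Mesp1, the first marker of cardiac mesoderm, at 16.2 ± 2.23 FPKM. The cardiac sarcomere genes Myh6 (122 ± 28.6 FPKM), Tnnt2 (168 ± 27.3) and Actc1 (304 ± 29.0) were abundant at day 8. Afp, made by visceral endoderm, was highest at day 12 with 404 ± 144 FPKM. These levels come from 6 tables that may have been normalized separately, so they were not tested across days.

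**Figure D2:**
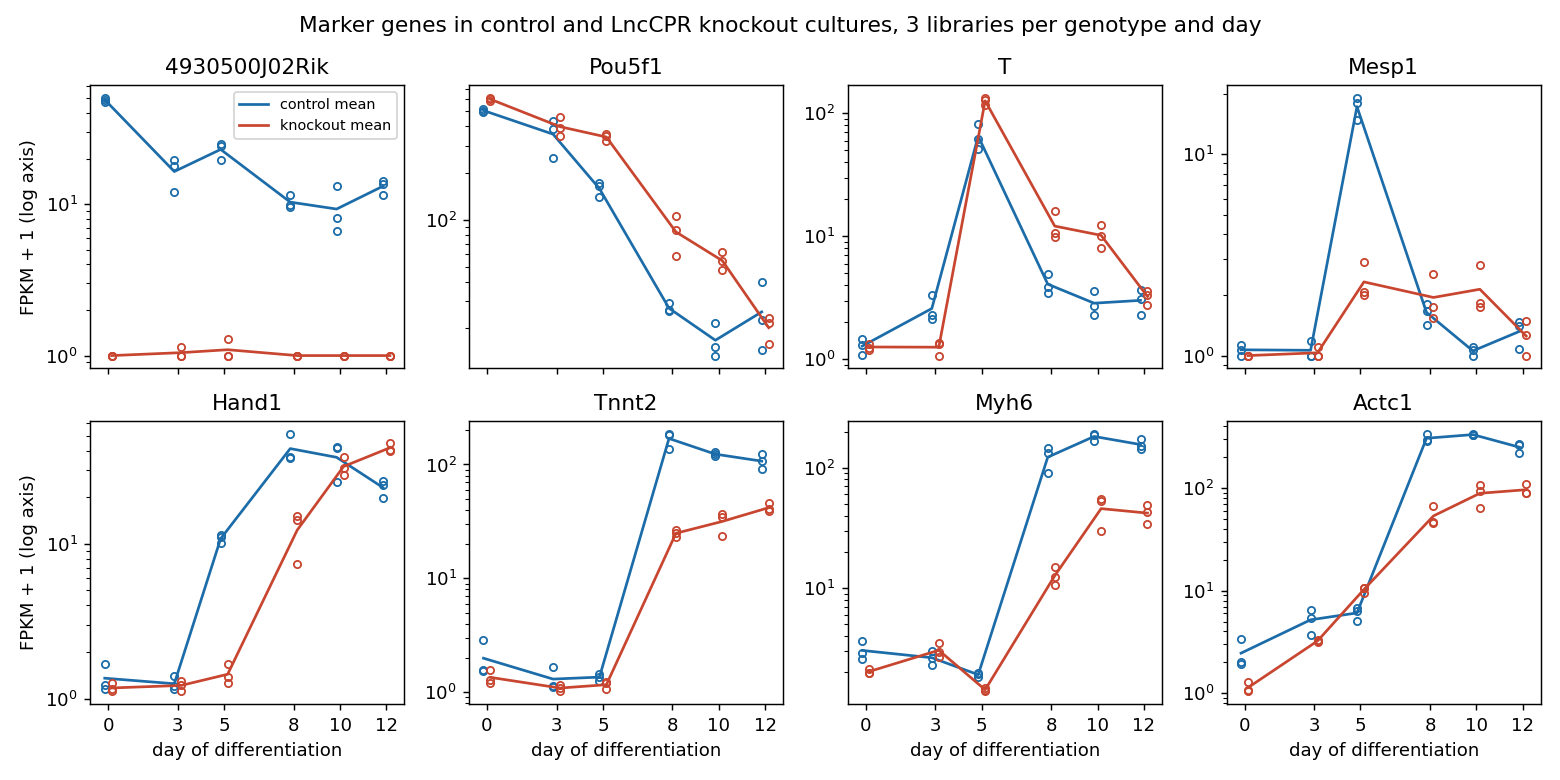
FPKM + 1 of 8 genes on a log axis, lines for means and points for libraries. Mesp1 at day 5 is 16.2 ± 2.23 FPKM in control and 1.32 ± 0.506 FPKM in knockout, and Myh6 at day 8 is 122 ± 28.6 FPKM in control and 11.7 ± 2.14 FPKM in knockout.

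The day 0 comparison asks whether stem cells lacking LncCPR differ before differentiation starts. They kept the core pluripotency genes. The naive-state factors Tbx3, Klf5 and Nr0b1 were higher, but the naive marker Dppa3 and the primed-state factor Otx2 were lower. A shift between these states was not tested. The low-oxygen genes Ankrd37, Ndrg1 and Egln3 and the imprinted RNAs H19 and Meg3 were lower, and the germline genes Dazl, Mael and Ddx4 were higher. Pou5f1 was slightly higher, at 505 ± 13.7 FPKM in control and 598 ± 12.9 FPKM in knockout (log2 fold change 0.24, SE 0.051, adjusted p = 0.0224), a call that ended in 4 of the 6 ways to leave out 1 library. Nanog (0.103, adjusted p = 0.259) and Zfp42 (-0.14, adjusted p = 0.176) did not pass the threshold. Values this small also depend on a gene's chromosome, since chromosomes 6 and 8 had shifts of -0.25 and -0.26 at day 0. Tbx3 lay at 29.3 ± 2.25 FPKM in control and 50.02 ± 3.53 FPKM in knockout (log2 fold change 0.75, SE 0.078, adjusted p = 0.0017). Nr0b1 lay at 18.9 ± 2.46 FPKM in control and 33.2 ± 0.371 FPKM in knockout (log2 fold change 0.79, SE 0.093, adjusted p = 0.00279). Klf5 (0.48, adjusted p = 0.00824) was higher too. Otx2 lay at 8.38 ± 0.291 FPKM in control and 4.58 ± 0.597 FPKM in knockout (log2 fold change -0.75, SE 0.103, adjusted p = 0.00475). Dppa3, which marks the most naive stem cells and protects methylation in the egg, was listed at 11.4 ± 1.49 FPKM in control and 1.23 ± 0.172 FPKM in knockout (log2 fold change -2.47, SE 0.12, adjusted p = 8.10e-05). The X-linked testis gene Tex13 lay at 23.1 ± 0.853 FPKM in control and 1.19 ± 0.573 FPKM in knockout (log2 fold change -3.49, SE 0.17, adjusted p = 8.10e-05).

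Among hypoxia genes, Ankrd37 (-1.05, adjusted p = 0.0059), Ndrg1 (-0.87, adjusted p = 0.00342) and the oxygen sensor Egln3 (-0.79, adjusted p = 0.00343) were lower. Hypoxia genes were called lower as a list, with 0 higher and 10 lower of 19 tested (0 and 13 adjusted over the list alone). For hypoxia genes the camera adjusted p was 2.72e-07, and adjusted p = 0.252 with an estimated correlation. The imprinted RNA Meg3 (-0.97, adjusted p = 0.00258) was lower. Imprinted genes were called lower as a list, with 4 higher and 10 lower of 25 tested (4 and 12 adjusted over the list alone). For imprinted genes the camera adjusted p was 0.0461, and adjusted p = 0.497 with an estimated correlation. The germline genes Dazl (0.78, adjusted p = 0.0017), Mael (0.56, adjusted p = 0.0049) and Ddx4 (0.41, adjusted p = 0.0111) were higher, but the germ cell list was not called, with 4 higher and 0 lower of 11 tested, 5 and 0 adjusted over the list alone (camera adjusted p = 0.0542). The testis-expressed genes D1Pas1 (1.36, adjusted p = 0.00264) and Rpl10l (1.45, adjusted p = 1.06e-04) were higher. The zinc-finger gene Zfp600 (1.22, adjusted p = 2.38e-04) and the phosphatase relative Dusp27 (1.45, adjusted p = 1.64e-04) were higher too. The epithelial genes Cdh1 (-0.61, adjusted p = 0.00113) and Cldn6 (-0.84, adjusted p = 0.00513) and the BMP target Id1 (-0.61, adjusted p = 0.0037) were lower. The epithelial list was not called, with 1 higher and 5 lower of 11 tested, 2 and 6 adjusted over the list alone (camera adjusted p = 0.0630). Nor was the list of BMP, Nodal and TGF-beta targets, with 0 higher and 3 lower of 13 tested, 0 and 3 adjusted over the list alone (camera adjusted p = 0.0816). Pluripotency genes were called higher as a list, with 8 higher and 2 lower of 25 tested (8 and 2 adjusted over the list alone). For pluripotency genes the camera adjusted p was 0.0498, and adjusted p = 0.347 with an estimated correlation. This call ended after rescaling (adjusted p = 0.0565). Also called were trophoblast genes, lower, and genes of the 2-cell-like state, higher (camera adjusted p = 0.0278 and 0.0263). With an estimated correlation their adjusted p = 0.323 and 0.323. The 2-cell-like genes had 2 higher and 0 lower of 3 tested (3 and 0 adjusted over the list alone).

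Of 12197 genes, 791 were higher and 979 lower at day 0, a total of 1770, and 27 and 45 of these by more than 2-fold. The count was 1041, 797 and 826 without control replicates 1, 2 and 3, and 952, 979 and 988 without knockout replicates 1, 2 and 3. After rescaling of libraries 49.3% of the genes past the threshold were higher, against 44.7% before. Without genes on chromosomes 1, 6 and 8 the balance turned, to 608 higher and 421 lower.

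Day 3 asks how the cells leave pluripotency. T and Fgf8, which turn on as the streak begins, were low in the knockout. T was too low to be tested, and the epiblast and streak list as a whole was not called. Some small nucleolar RNAs differed strongly, and some germline genes and the immunoproteasome gene Psmb8 were higher. T was listed at 1.59 ± 0.665 FPKM in control and 0.256 ± 0.159 FPKM in knockout, below the mean of 1 FPKM that a test required. Fgf8 lay at 3.35 ± 0.351 FPKM in control and 1.03 ± 0.576 FPKM in knockout (log2 fold change -1.14, SE 0.24, adjusted p = 0.00498). The imprinted gene Nnat lay at 14.9 ± 4.67 FPKM in control and 6.39 ± 1.02 FPKM in knockout (log2 fold change -1.06, SE 0.25, adjusted p = 0.015). Tex13 (-3.73, adjusted p = 1.39e-13) and H19 (-1.22, adjusted p = 0.00618) stayed lower. Fgf5 (0.26, adjusted p = 0.762), the marker of the formative epiblast, did not pass, nor did Pou5f1 (0.19, adjusted p = 0.857). Pou3f1 (0.94, adjusted p = 0.026), another formative factor, was higher. The epiblast and streak list had 1 higher and 1 lower of 11 tested, 2 and 2 adjusted over the list alone (camera adjusted p = 0.626).

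The immunoproteasome gene Psmb8 lay at 3.82 ± 1.18 FPKM in control and 16.0 ± 1.77 FPKM in knockout (log2 fold change 1.84, SE 0.24, adjusted p = 6.62e-06). The germline genes Mael (1.07, adjusted p = 0.00871) and Tex19.1 (1.19, adjusted p = 0.00486), silenced by methylation in somatic cells, were higher. So were the zinc-finger-region gene Gm13145 (1.64, adjusted p = 1.10e-04) and Dusp27 (1.08, adjusted p = 0.00599). SNORD56 (173 ± 60.2 FPKM in control and 13.8 ± 10.8 FPKM in knockout) was lower. Snord110 (53.1 ± 10.7 FPKM in control and 8.26 ± 7.34 FPKM in knockout) was lower and Snora52 (2.15 ± 2.45 FPKM in control and 15.7 ± 5.54 FPKM in knockout) higher, and such short RNAs respond to how libraries are size-selected. Germ cell genes were called higher as a list, with 2 higher and 0 lower of 11 tested (3 and 0 adjusted over the list alone). For germ cell genes the camera adjusted p was 0.0028, and adjusted p = 0.58 with an estimated correlation. Stress response genes were called higher as a list, with 1 higher and 0 lower of 16 tested (3 and 0 adjusted over the list alone). For stress response genes the camera adjusted p was 0.00405, and adjusted p = 0.637 with an estimated correlation. Neural genes were called lower as a list, with 0 higher and 0 lower of 12 tested (1 and 1 adjusted over the list alone). For neural genes the camera adjusted p was 0.0461, and adjusted p = 0.595 with an estimated correlation. Wnt target genes were called lower as a list, with 0 higher and 0 lower of 6 tested (0 and 0 adjusted over the list alone). For Wnt target genes the camera adjusted p was 0.0477, and adjusted p = 0.347 with an estimated correlation. After rescaling both calls ended (adjusted p = 0.0529 and 0.0995). The trophoblast and epithelial lists were called higher and Notch targets lower (adjusted p = 0.623, 0.685 and 0.429 with an estimated correlation). The imprinted list and the list of BMP, Nodal and TGF-beta targets were called lower (adjusted p = 0.732 and 0.719 with an estimated correlation). These calls ended after rescaling too (adjusted p = 0.0502 and 0.111). Their medians were 0.044 and 0.013 and their means -0.050 and -0.084, while the median of the genes tested was 0.15.

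At day 3, 130 of 11976 genes were higher and 80 lower, in total 210, and 332 passed without control replicate 3. The balance depends on scaling and on single libraries: 211 were higher and 335 lower after rescaling, and 93 and 159 without control replicate 1. The simulated test recovered 34.3% of log2 changes of 1 at this day. Without a filter on low values 2 genes passed. Of the 18 genes named for day 3, 2 passed without that filter, 4930500J02Rik and Tex13.

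Day 5 is the stage of the primitive streak and the first heart precursors. Mesp1, Kdr, Hand1, Hand2 and Gata4, genes of cardiac mesoderm, were far lower in the knockout. Pou5f1, Nanog and T itself, the marker of the streak, were higher, while the pluripotency list as a whole was not called. The p53 targets Ccng1 and Eda2r and the actin-binding Tagln were higher, and the matrix gene Fn1 was lower. Mesp1, which starts the cardiac programme, was listed at 16.2 ± 2.23 FPKM in control and 1.32 ± 0.506 FPKM in knockout (log2 fold change -2.90, SE 0.16, adjusted p = 1.95e-06). Kdr, the receptor on blood and heart precursors, was listed at 19.4 ± 2.33 FPKM in control and 0.927 ± 0.0757 FPKM in knockout (log2 fold change -3.39, SE 0.12, adjusted p = 9.88e-08). The heart factor Hand1 lay at 9.79 ± 0.669 FPKM in control and 0.435 ± 0.207 FPKM in knockout (log2 fold change -2.92, SE 0.14, adjusted p = 1.04e-06). Hand2 lay at 5.96 ± 0.885 FPKM in control and 0.0983 ± 0.0635 FPKM in knockout (log2 fold change -2.66, SE 0.14, adjusted p = 1.65e-06). Gata4 lay at 12.3 ± 1.43 FPKM in control and 3.41 ± 0.537 FPKM in knockout (log2 fold change -1.60, SE 0.13, adjusted p = 3.17e-05). Isl1 (-1.32, adjusted p = 2.03e-04) of the second heart field was lower as well. Cardiac progenitor genes were called lower as a list, with 1 higher and 13 lower of 16 tested (1 and 13 adjusted over the list alone). For cardiac progenitor genes the camera adjusted p was 1.99e-27, and adjusted p = 0.188 with an estimated correlation.

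The ligand gene Bmp5 (-2.93, adjusted p = 4.20e-06) and the BMP targets Msx1 (-1.07, adjusted p = 0.00106) and Msx2 (-1.44, adjusted p = 1.51e-04) were lower. The list of BMP, Nodal and TGF-beta targets was split and not called, with 5 higher and 4 lower of 15 tested, 7 and 6 adjusted over the list alone (camera adjusted p = 0.233). The Notch ligand gene of paraxial mesoderm, Dll1 (-2.27, adjusted p = 1.46e-06), was lower. Snai1 (-1.42, adjusted p = 9.00e-05), Zeb1 (-1.26, adjusted p = 2.43e-04) and Zeb2 (-0.88, adjusted p = 0.0021), which can drive the move from epithelium to mesenchyme, were lower. The matrix gene Fn1 lay at 143 ± 12.6 FPKM in control and 30.8 ± 3.64 FPKM in knockout (log2 fold change -2.19, SE 0.13, adjusted p = 2.35e-06). The chemokine receptor gene Cxcr4 (-1.65, adjusted p = 2.40e-05) and endodermal Sox17 (-0.79, adjusted p = 0.00168) were lower. Imprinted genes Igf2 (-2.15, adjusted p = 1.36e-05), Phlda2 (-2.46, adjusted p = 1.46e-06) and Peg10 (-1.23, adjusted p = 9.30e-05) were lower, and so was Capn6 (-3.32, adjusted p = 1.00e-07). Pou5f1 lay at 158 ± 16.9 FPKM in control and 341 ± 18.8 FPKM in knockout (log2 fold change 1.11, SE 0.14, adjusted p = 5.05e-04). Nanog (0.91, adjusted p = 0.00157), L1td1 (1.18, adjusted p = 2.32e-04) and Foxd3 (1.72, adjusted p = 1.77e-05) were higher with it. The pluripotency list had 8 higher and 1 lower of 23 tested, 9 and 2 adjusted over the list alone (camera adjusted p = 0.414). T lay at 64.2 ± 15.6 FPKM in control and 125 ± 8.44 FPKM in knockout (log2 fold change 0.98, SE 0.16, adjusted p = 0.0036). The epiblast and streak list was not called, with 9 higher and 5 lower of 21 tested, 12 and 6 adjusted over the list alone (camera adjusted p = 0.868). The BMP antagonist gene Chrd (1.35, adjusted p = 3.75e-05) of the anterior streak was higher. The actin-binding Tagln (1.45, adjusted p = 1.78e-04) and stress-responsive Ndrg1 (1.94, adjusted p = 2.94e-06) were higher. The p53 targets Ccng1 (0.63, adjusted p = 0.00488) and Eda2r (0.62, adjusted p = 0.00618) were higher.

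Parietal endoderm genes were called lower as a list, with 0 higher and 6 lower of 10 tested (0 and 7 adjusted over the list alone). For parietal endoderm genes the camera adjusted p was 4.09e-09, and adjusted p = 0.188 with an estimated correlation. Fibroblast genes were called lower as a list, with 0 higher and 5 lower of 10 tested (1 and 5 adjusted over the list alone). For fibroblast genes the camera adjusted p was 1.66e-06, and adjusted p = 0.252 with an estimated correlation. Imprinted genes were called lower as a list, with 4 higher and 8 lower of 22 tested (5 and 10 adjusted over the list alone). For imprinted genes the camera adjusted p was 8.15e-06, and adjusted p = 0.408 with an estimated correlation. Trophoblast genes were called lower as a list, with 1 higher and 2 lower of 8 tested (1 and 4 adjusted over the list alone). For trophoblast genes the camera adjusted p was 8.07e-05, and adjusted p = 0.35 with an estimated correlation. Notch target genes were called lower as a list, with 0 higher and 3 lower of 7 tested (0 and 3 adjusted over the list alone). For Notch target genes the camera adjusted p was 1.01e-04, and adjusted p = 0.252 with an estimated correlation.

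p53 target genes were called higher as a list, with 9 higher and 0 lower of 15 tested (12 and 0 adjusted over the list alone). For p53 target genes the camera adjusted p was 2.73e-05, and adjusted p = 0.349 with an estimated correlation. After rescaling 5 of the p53 target genes were higher. Smooth muscle genes were called higher as a list, with 3 higher and 0 lower of 6 tested (3 and 0 adjusted over the list alone). For smooth muscle genes the camera adjusted p was 0.00704, and adjusted p = 0.252 with an estimated correlation. Blood genes, with the progenitor gene Lmo2 (0.83, adjusted p = 0.00618), and stress genes, with Atf3 (1.11, adjusted p = 4.22e-04), were called higher (adjusted p = 0.40 and 0.40 with an estimated correlation). The endoderm list was called lower with a median of 0.084 and a mean of -0.15 (adjusted p = 0.409 with an estimated correlation, and 0.0999 after rescaling). Of 12447 genes, 880 were higher and 413 lower, a total of 1293, which was 833 without knockout replicate 3 and 843 without control replicate 1. After rescaling 43.0% of the genes past the threshold were higher, against 68.1% before, so the excess of higher genes depends on scaling. The predicted genes Gm16869, Gm10717 and Gm10801 were lower with SDs of 414, 134 and 43.9 FPKM among the controls, and are not read further.

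Day 8 is when heart muscle appears in the control. In the knockout Myh6, Myl2, Tnnt2, Actc1 and other contractile genes were far lower, together with the embryonic globins Hbb-bh1 and Hba-x and the mesenchymal genes Col3a1 and Pdgfra. Pou5f1, Fgf5, Dnmt3b, T and L1td1 were higher, while the pluripotency list as a whole was not called. The early myosin Myh6 lay at 122 ± 28.6 FPKM in control and 11.7 ± 2.14 FPKM in knockout (log2 fold change -3.26, SE 0.20, adjusted p = 3.88e-05). The ventricular light chain gene Myl2 lay at 26.7 ± 4.28 FPKM in control and 1.54 ± 0.688 FPKM in knockout (log2 fold change -3.48, SE 0.22, adjusted p = 3.88e-05). Tnnt2 lay at 168 ± 27.3 FPKM in control and 23.9 ± 1.73 FPKM in knockout (log2 fold change -2.75, SE 0.15, adjusted p = 3.88e-05). Actc1 lay at 304 ± 29.0 FPKM in control and 52.4 ± 12.0 FPKM in knockout (log2 fold change -2.53, SE 0.17, adjusted p = 4.52e-05). Further sarcomere genes were lower, with Tnni1 (-2.94, adjusted p = 6.79e-05), Mybpc3 (-2.43, adjusted p = 9.94e-05) and Myl7 (-2.36, adjusted p = 2.61e-04). So were Myh7 (-1.997, adjusted p = 3.88e-05) and the muscle chaperone gene Hspb7 (-2.15, adjusted p = 1.10e-04). Cardiomyocyte genes were called lower as a list, with 0 higher and 23 lower of 30 tested (0 and 26 adjusted over the list alone). For cardiomyocyte genes the camera adjusted p was 1.99e-46, and adjusted p = 0.186 with an estimated correlation.

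The heart factors Hand2 (-1.82, adjusted p = 5.43e-04), Mef2c (-1.67, adjusted p = 6.23e-04) and Tbx5 (-1.15, adjusted p = 0.00983) were lower, as was Gata4 (-0.71, adjusted p = 0.0261), a call that ended in 5 of the 6 ways to leave out 1 library. Isl1 (-0.009, adjusted p = 0.984) and Nkx2-5 (-0.65, adjusted p = 0.11) did not pass. Cardiac progenitor genes were called lower as a list, with 1 higher and 13 lower of 25 tested (1 and 19 adjusted over the list alone). For cardiac progenitor genes the camera adjusted p was 2.18e-20, and adjusted p = 0.186 with an estimated correlation. The embryonic globin Hbb-bh1 lay at 15.2 ± 1.46 FPKM in control and 0.429 ± 0.435 FPKM in knockout (log2 fold change -3.55, SE 0.23, adjusted p = 3.88e-05). Hba-x (-3.32, adjusted p = 3.88e-05), another globin, was lower. The vessel genes Kdr (-0.81, adjusted p = 0.0102) and Cdh5 (-0.79, adjusted p = 0.0102) were lower, and both calls ended without control replicate 2, that of Kdr without knockout replicate 1 as well. The mesenchymal genes Col3a1 (-1.95, adjusted p = 1.72e-04) and Pdgfra (-1.62, adjusted p = 2.56e-04) and the imprinted growth inhibitor gene Cdkn1c (-1.48, adjusted p = 4.42e-04) were lower. Pou5f1 lay at 26.0 ± 1.72 FPKM in control and 82.6 ± 23.4 FPKM in knockout (log2 fold change 1.59, SE 0.20, adjusted p = 0.00176). Fgf5 (1.42, adjusted p = 4.21e-04), Dnmt3b (1.403, adjusted p = 0.00425) and T (1.55, adjusted p = 0.00394) were higher. So were L1td1 (1.30, adjusted p = 3.14e-04) and the kinase gene Pim2 (2.06, adjusted p = 7.83e-05). Neural Zic5 (1.60, adjusted p = 0.00206) and Stmn2 (1.46, adjusted p = 0.00107) were higher too, as was the p53 target Ccng1 (0.86, adjusted p = 0.013), a call that ended in 3 of the 6 ways to leave out 1 library. The neural list was not called, with 2 higher and 1 lower of 9 tested, 2 and 2 adjusted over the list alone (camera adjusted p = 0.598). The pluripotency list had 5 higher and 0 lower of 22 tested, 7 and 1 adjusted over the list alone (camera adjusted p = 0.402).

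Epiblast and streak genes were called higher as a list, with 6 higher and 0 lower of 17 tested (11 and 0 adjusted over the list alone). For epiblast and streak genes the camera adjusted p was 7.69e-08, and adjusted p = 0.252 with an estimated correlation. Fibroblast genes were called lower as a list, with 0 higher and 6 lower of 20 tested (0 and 10 adjusted over the list alone). For fibroblast genes the camera adjusted p was 1.10e-10, and adjusted p = 0.188 with an estimated correlation. Endothelial genes were called lower as a list, with 0 higher and 4 lower of 18 tested (0 and 10 adjusted over the list alone). For endothelial genes the camera adjusted p was 4.82e-10, and adjusted p = 0.188 with an estimated correlation. p53 target genes were called higher as a list, with 6 higher and 0 lower of 15 tested (12 and 0 adjusted over the list alone). For p53 target genes the camera adjusted p was 1.42e-08, and adjusted p = 0.252 with an estimated correlation. Blood genes were called lower as a list, with 1 higher and 3 lower of 9 tested (2 and 4 adjusted over the list alone). For blood genes the camera adjusted p was 0.00725, and adjusted p = 0.252 with an estimated correlation.

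Epithelial genes were called higher as a list, with 2 higher and 0 lower of 13 tested (3 and 0 adjusted over the list alone). For epithelial genes the camera adjusted p was 0.00376, and adjusted p = 0.35 with an estimated correlation. BMP and Nodal targets were called lower as a list, with 1 higher and 4 lower of 18 tested (1 and 5 adjusted over the list alone). For BMP and Nodal targets the camera adjusted p was 0.00772, and adjusted p = 0.543 with an estimated correlation. Small structured RNAs were called lower as a list, with 0 higher and 0 lower of 7 tested (0 and 1 adjusted over the list alone). For small structured RNAs the camera adjusted p was 0.0353, and adjusted p = 0.637 with an estimated correlation. Cell cycle and mitochondrial genes were called higher (adjusted p = 0.487 and 0.519 with an estimated correlation). Imprinted, parietal endoderm, endoderm and Wnt target genes were called lower (adjusted p = 0.29, 0.35, 0.721 and 0.323 with an estimated correlation), and the endoderm call ended after rescaling (adjusted p = 0.0669). Of 12695 genes, 163 were higher and 254 lower, 417 in total. Without control replicates 1, 2 and 3 the count was 226, 190 and 247, and without knockout replicates 1, 2 and 3 it was 220, 268 and 665. The balance turned without knockout replicate 3, to 406 higher and 259 lower, and in 1 fit of all 36 libraries, to 648 and 563, and was 296 and 294 with a replicate block. Of the 67 genes named for day 8 by the rule and past the threshold, 38 passed whichever 1 library was left out.

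At day 10 the heart muscle genes Myh6, Myl2 and Tnnt2 stayed lower. The collagen genes Col3a1, Col5a2 and Col6a3 and the endoderm genes Afp, Trf and Rbp4 were lower, and Pou5f1, Nanog, T and Fgf8 were higher. Myh6 lay at 181 ± 14.6 FPKM in control and 44.8 ± 14.1 FPKM in knockout (log2 fold change -2.04, SE 0.20, adjusted p = 3.46e-05). Myl2 lay at 56.8 ± 8.27 FPKM in control and 6.76 ± 1.89 FPKM in knockout (log2 fold change -2.92, SE 0.18, adjusted p = 9.38e-07). Tnni3 (-2.26, adjusted p = 4.47e-06), Tnnt2 (-1.99, adjusted p = 9.94e-06) and Actc1 (-1.93, adjusted p = 1.84e-05) were lower. Cardiomyocyte genes were called lower as a list, with 1 higher and 26 lower of 32 tested (1 and 27 adjusted over the list alone). For cardiomyocyte genes the camera adjusted p was 3.74e-36, and adjusted p = 0.188 with an estimated correlation. The 1 higher member is Ttn, listed at 0 in the 3 controls and at 19.01 ± 3.96 FPKM in the knockout. It was also listed at 0 in 2 of 3 control libraries of day 8, so these zeros are not read as absence of the transcript. The heart factors Tbx5 (-1.35, adjusted p = 2.40e-04), Hand2 (-1.38, adjusted p = 8.72e-05) and Nkx2-5 (-1.02, adjusted p = 0.00134) and the mesendoderm factor Gata6 (-1.17, adjusted p = 1.82e-04) were lower. Cardiac progenitor genes were called lower as a list, with 1 higher and 14 lower of 23 tested (1 and 14 adjusted over the list alone). For cardiac progenitor genes the camera adjusted p was 5.35e-13, and adjusted p = 0.26 with an estimated correlation.

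The collagen genes Col5a2 (-2.77, adjusted p = 4.22e-06) and Col6a3 (-2.36, adjusted p = 2.45e-06) and the matrix genes Lum (-2.15, adjusted p = 3.33e-05) and Dcn (-2.06, adjusted p = 1.84e-05) were lower. Col3a1 lay at 129 ± 23.1 FPKM in control and 26.0 ± 2.86 FPKM in knockout (log2 fold change -2.26, SE 0.15, adjusted p = 2.38e-06). Fibroblast genes were called lower as a list, with 0 higher and 17 lower of 24 tested (0 and 18 adjusted over the list alone). For fibroblast genes the camera adjusted p was 7.14e-24, and adjusted p = 0.252 with an estimated correlation. The endoderm marker Afp lay at 287 ± 57.9 FPKM in control and 80.04 ± 17.5 FPKM in knockout (log2 fold change -1.83, SE 0.19, adjusted p = 3.92e-05). The transferrin gene Trf (-2.44, adjusted p = 3.91e-05) and the retinol carrier gene Rbp4 (-1.57, adjusted p = 1.69e-04) were lower. Endoderm genes were called lower as a list, with 1 higher and 13 lower of 27 tested (3 and 16 adjusted over the list alone). For endoderm genes the camera adjusted p was 3.64e-10, and adjusted p = 0.347 with an estimated correlation. Imprinted Plagl1 (-1.90, adjusted p = 4.22e-06) and Dlk1 (-1.36, adjusted p = 8.25e-05) were lower.

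Pou5f1 lay at 15.8 ± 4.42 FPKM in control and 53.6 ± 7.26 FPKM in knockout (log2 fold change 1.73, SE 0.18, adjusted p = 4.43e-05). Nanog (1.55, adjusted p = 9.87e-05), Tdgf1 (1.75, adjusted p = 5.09e-05) and Lin28a (1.12, adjusted p = 4.42e-04) were higher. Pluripotency genes were called higher as a list, with 14 higher and 0 lower of 22 tested (14 and 2 adjusted over the list alone). For pluripotency genes the camera adjusted p was 1.52e-04, and adjusted p = 0.40 with an estimated correlation. The streak genes T (1.83, adjusted p = 8.72e-05) and Fgf8 (1.80, adjusted p = 1.02e-05) and the epiblast genes Fgf5 (1.55, adjusted p = 2.81e-04) and Dnmt3b (1.63, adjusted p = 1.44e-05) were higher. Epiblast and streak genes were called higher as a list, with 13 higher and 0 lower of 16 tested (14 and 0 adjusted over the list alone). For epiblast and streak genes the camera adjusted p was 1.19e-08, and adjusted p = 0.252 with an estimated correlation. The hormone gene Trh (2.46, adjusted p = 4.10e-06), the channel gene Kcnj3 (1.81, adjusted p = 5.63e-05) and the replication gene Mcm5 (0.80, adjusted p = 0.00306) were higher.

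Neural crest genes were called lower as a list, with 0 higher and 3 lower of 5 tested (0 and 3 adjusted over the list alone). For neural crest genes the camera adjusted p was 0.0033, and adjusted p = 0.252 with an estimated correlation. Cell cycle genes were called higher as a list, with 18 higher and 0 lower of 28 tested (23 and 0 adjusted over the list alone). For cell cycle genes the camera adjusted p was 2.32e-07, and adjusted p = 0.518 with an estimated correlation. Ribosomal protein genes were called higher as a list, with 14 higher and 0 lower of 28 tested (21 and 0 adjusted over the list alone). For ribosomal protein genes the camera adjusted p was 6.20e-05, and adjusted p = 0.505 with an estimated correlation. After rescaling 8 of the ribosomal protein genes were higher. Endothelial, parietal endoderm, imprinted and smooth muscle genes were called lower (adjusted p = 0.347, 0.40, 0.40 and 0.43 with an estimated correlation). Of 12938 genes, 1946 were higher and 663 lower, 2609 in total, and the total was 1540 without knockout replicate 2 and 1656 without knockout replicate 1. The excess of higher genes depends on scaling: 74.6% of them were higher, and 46.1% after rescaling.

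By day 12 Pou5f1, Nanog and T overlapped between the lines, while the heart muscle genes Myl2 and Myh6 and the matrix genes Col6a3, Dcn and Lum stayed lower. Pou5f1 lay at 24.5 ± 12.9 FPKM in control and 19.2 ± 3.9 FPKM in knockout (log2 fold change -0.24, SE 0.31, adjusted p = 0.691). Nanog (-0.21, adjusted p = 0.667) and T (0.12, adjusted p = 0.766) overlapped as well. The pluripotency list had 1 higher and 1 lower of 22 tested, 1 and 1 adjusted over the list alone (camera adjusted p = 0.427), and the epiblast and streak list 1 higher and 1 lower of 13 tested, 1 and 2 adjusted over the list alone (0.367). Myl2 lay at 90.5 ± 16.4 FPKM in control and 8.96 ± 1.32 FPKM in knockout (log2 fold change -3.19, SE 0.15, adjusted p = 1.22e-05). Myh6 lay at 155 ± 15.8 FPKM in control and 41.0 ± 7.78 FPKM in knockout (log2 fold change -1.90, SE 0.15, adjusted p = 3.45e-04). The sarcomere genes Tnni3 (-2.05, adjusted p = 5.85e-04), Myl3 (-1.78, adjusted p = 3.48e-04) and Mybpc3 (-1.64, adjusted p = 5.85e-04) were lower, as was Actc1 (-1.38, adjusted p = 5.85e-04). Cardiomyocyte genes were called lower as a list, with 0 higher and 24 lower of 33 tested (1 and 25 adjusted over the list alone). For cardiomyocyte genes the camera adjusted p was 1.60e-22, and adjusted p = 0.188 with an estimated correlation. Gata6 (-0.90, adjusted p = 0.00188) was lower, and Hand1 was now higher, at 22.1 ± 2.95 FPKM in control and 40.7 ± 2.84 FPKM in knockout (log2 fold change 0.86, SE 0.12, adjusted p = 0.00481). Cardiac progenitor genes were called lower as a list, with 1 higher and 6 lower of 23 tested (2 and 8 adjusted over the list alone). For cardiac progenitor genes the camera adjusted p was 1.75e-04, and adjusted p = 0.408 with an estimated correlation.

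Collagen Col6a3 lay at 22.8 ± 1.96 FPKM in control and 1.77 ± 0.371 FPKM in knockout (log2 fold change -3.11, SE 0.14, adjusted p = 1.22e-05). Dcn (-2.53, adjusted p = 6.55e-04), Lum (-1.90, adjusted p = 0.00129) and the epicardial factor Tcf21 (-1.81, adjusted p = 0.00169) were lower. Fibroblast genes were called lower as a list, with 0 higher and 18 lower of 25 tested (0 and 21 adjusted over the list alone). For fibroblast genes the camera adjusted p was 4.72e-23, and adjusted p = 0.188 with an estimated correlation. The phosphodiesterase gene Pde1a (-2.62, adjusted p = 3.45e-04) and the globin Hba-x (-1.55, adjusted p = 0.00227) were lower. The vessel genes Pecam1 (-0.85, adjusted p = 0.00756) and Cd34 (-1.13, adjusted p = 0.00524) and the blood factor gene Runx1 (-0.94, adjusted p = 0.00932) were lower. The mitochondrial transcripts mt-Nd2 (-1.06, adjusted p = 0.00169) and mt-Cytb (-1.002, adjusted p = 0.00151) were lower. The gut hormone gene Pyy lay at 0.833 ± 0.688 FPKM in control and 21.2 ± 1.81 FPKM in knockout (log2 fold change 3.66, SE 0.23, adjusted p = 1.44e-04). Prtg (1.45, adjusted p = 2.97e-04) of early neural and mesodermal tissue, Lin28a (1.19, adjusted p = 3.48e-04) and Msx2 (0.95, adjusted p = 0.00318) were higher. The mitotic genes Cdc20 (0.75, adjusted p = 0.00484), Plk1 (0.61, adjusted p = 0.0109) and Bub1b (0.64, adjusted p = 0.00964) and the carbonic anhydrase gene Car4 (1.24, adjusted p = 3.45e-04) were higher.

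Endothelial genes were called lower as a list, with 0 higher and 3 lower of 18 tested (0 and 9 adjusted over the list alone). For endothelial genes the camera adjusted p was 5.38e-07, and adjusted p = 0.347 with an estimated correlation. Mitochondrial transcripts were called lower as a list, with 0 higher and 7 lower of 13 tested (0 and 9 adjusted over the list alone). For mitochondrial transcripts the camera adjusted p was 6.70e-07, and adjusted p = 0.208 with an estimated correlation. Cell cycle genes were called higher as a list, with 15 higher and 0 lower of 28 tested (21 and 0 adjusted over the list alone). For cell cycle genes the camera adjusted p was 8.44e-10, and adjusted p = 0.252 with an estimated correlation. Ribosomal protein genes were called higher as a list, with 5 higher and 0 lower of 28 tested (8 and 0 adjusted over the list alone). For ribosomal protein genes the camera adjusted p was 4.66e-05, and adjusted p = 0.285 with an estimated correlation. Blood, parietal endoderm, endoderm and imprinted genes were called lower (adjusted p = 0.397, 0.40, 0.737 and 0.658 with an estimated correlation). Wnt targets were called higher (adjusted p = 0.347 with an estimated correlation, and 0.0502 after rescaling).

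Of 13089 genes at day 12, 422 were higher and 456 lower, 878 in total. The total was 440, 583 and 493 without control replicates 1, 2 and 3, and 370, 317 and 333 without knockout replicates 1, 2 and 3. After rescaling 36.9% of the genes past the threshold were higher, against 48.1% before. Without genes on chromosomes 1, 6 and 8, 315 were higher and 294 lower, and at a mean of 5 FPKM or more 386 and 285.

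**Figure D3:**
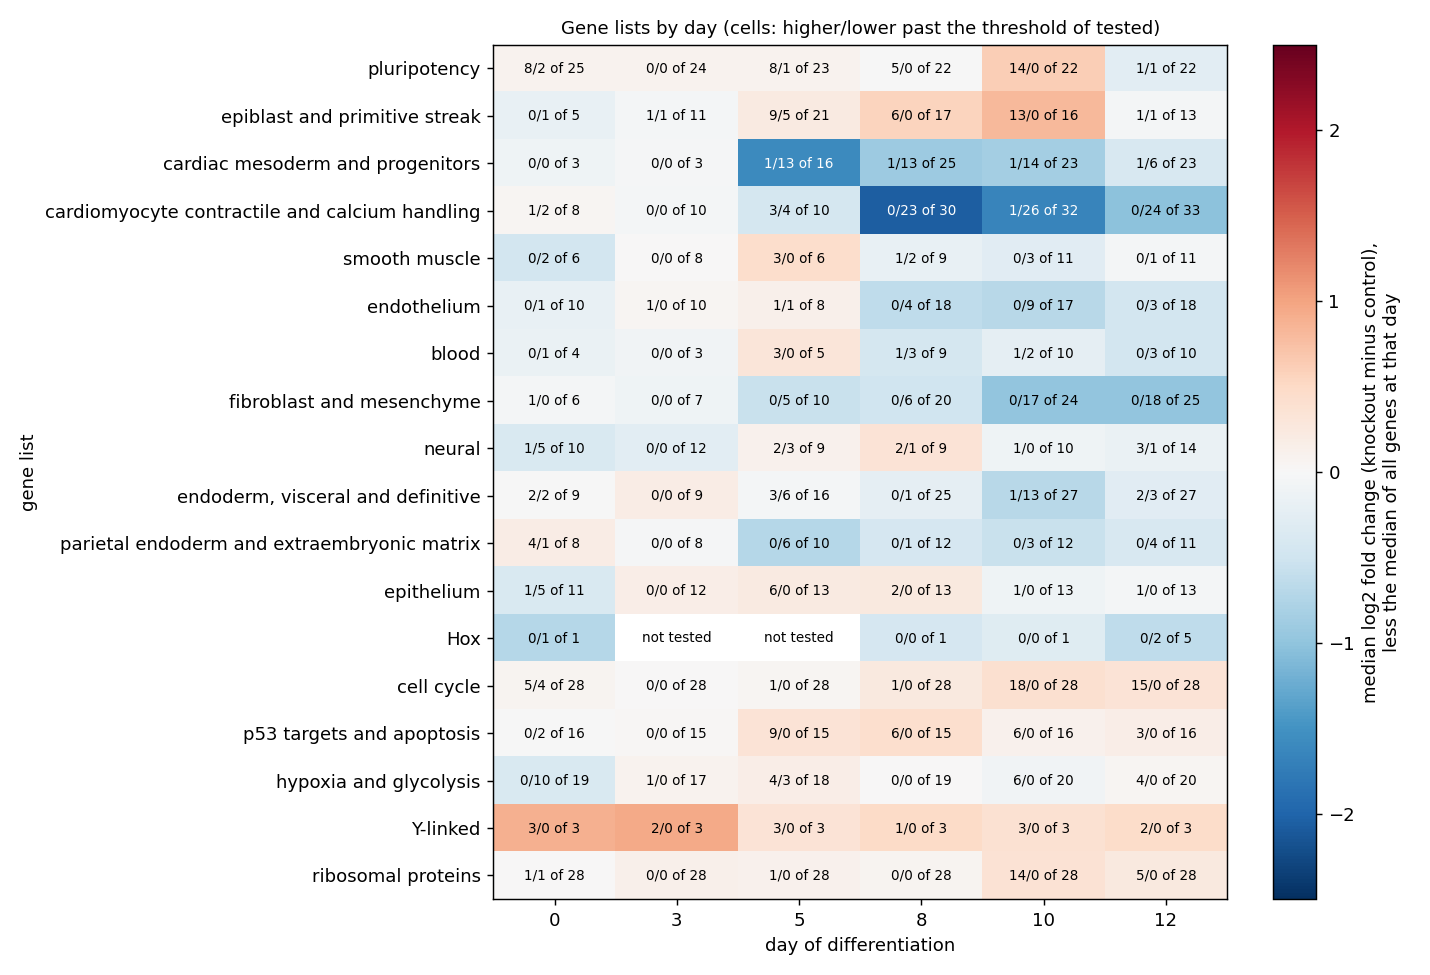
Median log2 fold change of 18 gene lists at each day, minus the median of the genes tested that day, with the numbers higher and lower of those tested. The cardiomyocyte list has -2.05 at day 8, -1.66 at day 10 and -1.03 at day 12.

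3 of the 31 lists were not called at any day. Skeletal muscle had 2 higher and 0 lower of 3 tested at day 12 (camera adjusted p = 0.106) and Hox genes 0 higher and 2 lower of 5 tested (camera adjusted p = 0.0840), with Hoxc8 (-0.996, adjusted p = 0.0373) and Hoxa10 (-0.92, adjusted p = 0.0362) lower. X inactivation had 1 or 2 genes tested per day, too few for camera. Over the 162 combinations tested, 72 were called, 65 of 162 after rescaling, and 0 with an estimated correlation. A further 32 combinations in which the median, mean and test differ in sign were not called.

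The last comparison asks for which genes the difference between the lines changes from day to day. A change in the control line enters this test too. The medians of chromosomes 1, 6 and 8 moved in the control line between days 3 and 5, so the calls are not all responses to the knockout. The lowest p values belonged to Col6a3 (adjusted p = 7.52e-15), Capn6 (1.59e-13), Hspb7 (7.79e-13), Bmp5 (4.09e-12), Tex13 (5.32e-12), Prtg (5.86e-12) and Mybpc3 (5.43e-11). Prtg shows the reversal some genes made, at 70.9 ± 6.59 FPKM in control and 33.0 ± 2.78 FPKM in knockout on day 5 and 26.2 ± 2.21 FPKM in control and 73.4 ± 4.62 FPKM in knockout on day 12. Hand1 moved from -2.92 at day 5 to 0.86 at day 12 (adjusted p between days 2.28e-10), and Ndrg1 from -0.87 at day 0 to 1.94 at day 5. The limma F test called 2229 of 13022 genes. The count was 1312 without day 0, 4203 after median-ratio rescaling and 4197 after quantile normalization. The F test takes the spread of a gene as the same at all days. In the fits of single days the median SE ran from 0.106 at day 0 to 0.243 at day 3, so unequal spread may add to the calls. The fold changes of neighbouring days correlated across genes at r = 0.35 between days 0 and 3, 0.12 between days 3 and 5, 0.42 between days 5 and 8, 0.57 between days 8 and 10 and 0.48 between days 10 and 12. Between days 0 and 12 it was 0.044, genes not being independent replicates.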

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

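Chosen after their results had been seen were the tests on the scaling of whole libraries, on the region around 4930500J02Rik and on the depth of the knockout libraries, and a bootstrap over steady genes. The remaining tests below were written before their results were seen.

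The difference between the lines changed between days, by the F test over 36 libraries, for 31 genes. They come from the panel, the all-day genes and the leading genes of that test. The panel was fixed with many heart genes, so their share of the 31 says nothing about which genes differ most. Heart muscle genes and heart factors are Hspb7 7.79e-13, Mybpc3 5.43e-11, Myh6 1.65e-10, Hand1 2.28e-10, Actc1 5.29e-09, Tnnt2 1.34e-08, Tbx5 3.04e-08, Myh7 2.81e-06, Isl1 8.32e-06, Gata4 1.87e-05, Myl7 2.57e-05 and Nkx2-5 0.00017 (adjusted p). Streak, epiblast and pluripotency genes follow with Mesp1 9.96e-11, T 8.48e-08, Fgf5 3.2e-07, Nanog 2.63e-06 and Pou5f1 0.000105. Matrix and mesoderm genes are Col6a3 7.52e-15, Capn6 1.59e-13, Bmp5 4.09e-12, Prtg 5.86e-12, Col5a2 6.02e-11 and Adamts9 9e-11. The others are Tex13 5.32e-12, Dusp27 6.02e-11, 4930500J02Rik 4e-08, Afp 0.000124, H19 0.0017, Ddx3y 0.00188, Pax6 0.00289 and Pecam1 0.00736. With the knockout near 0 throughout, the value of 4930500J02Rik restates how its control level varied between tables that may have been normalized separately. For scale, log2 fold changes were -3.26 for Myh6 at day 8, -2.90 for Mesp1 at day 5 and -3.11 for Col6a3 at day 12, with 3 of 3 knockout libraries below the controls.

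Chromosomes 6 and 8 lay lower in the knockout at days 0 and 3, and chromosome 1 at days 5 to 12. A few strongly changed genes could not shift a median in this way, and the lowest share of genes below the other chromosomes' median was 82.75%. The chromosomes were picked for their shifted medians, so this share restates the pattern and adds no separate evidence. GC content and transcript length are argued against by the 92.89% of the shift that stayed after a fit on both, for the 97.38% of genes with known values. Among genes steady in the control, 78.74% of the shift stayed at the lowest (chromosome 1, day 12), which misses the bound of 80% set before; a bootstrap added later put the lower limits at 63.6% or higher, so a response to differentiation is argued against as the whole cause. The change within the control line from day 3 to day 5, -0.2371 for chromosome 8, is what different cultures of the control line before and after day 3 would give, and gain of chromosome 8 is a known change of stem cells in culture. A mixture of cells with an extra copy may explain shifts smaller than the -0.58 that loss of 1 of 3 copies would give, and copy number was not measured.

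Cardiac genes were lower in the knockout at days 8 to 12, 73 lower calls of the cardiomyocyte list. Of these calls 100% passed after median-ratio rescaling, but this test could hardly fail. The genes tested had median log2 fold changes of 0.092, 0.17 and 0.054 at days 8, 10 and 12, so rescaling moved fold changes further down. Scaling as these medians show it did not lower the calls. Off chromosomes 1, 6 and 8 lay 86.3% of the calls, with a median log2 fold change of -1.70. At day 8 chromosomes 1, 6 and 8 held 701, 577 and 646 of 12368 genes with a known chromosome, so a high share is no evidence. Gene dosage there cannot directly lower calls that lie elsewhere, and an indirect effect of dosage was not tested. A delay of the whole differentiation by up to 4 days, as the only cause, is argued against by the cardiomyocyte list. Its median over 29 genes of knockout day 12 minus control day 8 was -1.392 ± 0.177 (SD, n = 3, -1.59 to -1.26 over libraries). For control day 12 minus control day 8 it was -0.30 (-0.41 to -0.19). Both are set across tables that may have been normalized separately. The test covers this list alone, so a delay combined with fewer heart muscle cells could give the same value. Pou5f1 and T, higher in the knockout at day 10 and overlapping at day 12, were not part of it. Still open are a delay as part of the cause, fewer cells entering cardiac mesoderm at day 5, the culture history of the lines, a property of the knockout clone, and loss of LncCPR itself. With the number of knockout clones not stated and chromosome medians that moved in the control line after day 3, the last 3 could each contribute, and the tables hold no rescue.

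4930500J02Rik was at or near 0 in the knockout libraries. Loss of a wider region around the gene is argued against by the lowest daily median of its expressed neighbours, 0.02614, and lower depth of the knockout libraries by their relative depth, 1.123 times that of the control. A median over the neighbours cannot exclude loss of a single adjacent gene. The bound for the neighbours was at first symmetrical about 0; the day 3 median of 0.33 lay above it, and it was made one-sided after that was seen. A deletion made at this gene, which may then be LncCPR under another name, and a silencing of it in the knockout clone stay open, since the tables hold no reads over the locus.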

How the results depend on the processing

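At day 0 the 1770 genes became 774 without a filter on low values, 824 with a replicate block, 557 in 1 fit of all 36 libraries, and 1029 without genes on chromosomes 1, 6 and 8. Leaving out control replicates 1, 2 and 3 gave 1041, 797 and 826, and knockout replicates 952, 979 and 988. At day 3 the 210 genes became 2 without a filter, 546 with median-ratio rescaling, 573 with quantile normalization, 342 with a replicate block, 985 in 1 fit of all 36 libraries, 319 with robust eBayes, 332 without control replicate 3, 186 without knockout replicate 1, and 34 without libraries whose top 10 genes hold over 20% of the sum. That last fit keeps 1 control library against 3 knockout libraries, so it cannot be weighed. At day 5 the 1293 became 424 without a filter, 843 without control replicate 1, which is also the library dominated by 10 genes, 833 without knockout replicate 3 and 996 without knockout replicate 2.

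At day 8 the 417 genes became 136 without a filter, 248 at a mean of 5 FPKM or more, 734 with median-ratio rescaling, 686 with quantile normalization, 1211 in 1 fit of all 36 libraries and 1326 without the dominated libraries, which leaves 2 control libraries and 1 knockout library and cannot be weighed either. Leaving out control replicates 1, 2 and 3 gave 226, 190 and 247, and knockout replicates 220, 268 and 665. At day 10 the 2609 became 775 without a filter, 1656 without knockout replicate 1 1540 without knockout replicate 2 and 2574 without control replicate 2. At day 12 the 878 became 218 without a filter, 464 with a replicate block and 333 without the dominated libraries. Leaving out control replicates 1, 2 and 3 gave 440, 583 and 493, and knockout replicates 370, 317 and 333.

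The 3 genes of all 6 days became 1 without a filter and 1 at a mean of 5 FPKM or more. The 2229 genes differing between days became 1293 at a mean of 5 FPKM or more, 4203 with median-ratio rescaling, 4197 with quantile normalization and 1312 without day 0. The 72 list calls became 0 with an estimated correlation. The cause of these moves was not tested.

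Of 7745 values for 473 named results, 6625 kept their reading, 1085 were weaker, 35 stronger and 0 reversed. Of the 430 named results past the threshold, 222 ended without a filter, and 272 stayed past it whichever 1 library was left out. By day these 272 were 39 of 69 at day 0, 11 of 18 at day 3, 72 of 91 at day 5, 38 of 67 at day 8, 68 of 99 at day 10 and 44 of 86 at day 12. The medians of 114 of 114 marker levels lay within 1 SD of the mean, which any median must, so this is no check of the levels.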

Other observations

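The list of interferon-stimulated genes, the 4 zinc-finger genes of chromosome 4 and the test on Igf2 were chosen only after the results had been seen.

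Some genes of antigen processing and the interferon response were higher in the knockout at middle days, which the lists fixed beforehand did not cover. Psmb8 had log2 fold changes of 1.84 at day 3 (adjusted p = 6.62e-06), 0.41 at day 5 (adjusted p = 0.154, not past the threshold), 1.55 at day 8 and 1.23 at day 10, each with 3 libraries per group. Gbp2 had 1.51, 1.05, 1.42 and 1.16 at these days. A list of 38 such genes had 0 higher and 3 lower of 21 tested at day 0 (camera adjusted p = 0.307). It had 5 higher and 0 lower of 24 tested at day 3 (camera adjusted p = 3.13e-11, and adjusted p = 0.267 with an estimated correlation), and 11 higher and 1 lower of 27 at day 5 (0.00292, and adjusted p = 0.391 with an estimated correlation). At day 8 it had 6 higher and 0 lower of 28 (1.24e-05, and adjusted p = 0.267 with an estimated correlation). At day 10 it had 9 higher and 2 lower of 29 with an adjusted p of 0.2274, and at day 12 it was called lower with 2 higher and 6 lower of 33 (adjusted p = 0.00568, and adjusted p = 0.322 with an estimated correlation), where Ifit1 (-1.15) and Oasl2 (-1.10) were lower. A response shared by the list may exist at days 3 to 8, but the tables leave it undecided over days 3 to 10.

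4 zinc-finger genes or their neighbours on chromosome 4 in GRCm38, Zfp534, Gm13145, Gm13051 and Zfp600, were higher in the knockout early and less so later. Log2 fold changes at days 0, 3 and 5 were 1.06, 1.496 and 0.64 for Zfp534, 1.06, 1.64 and 0.61 for Gm13145, 1.02, 1.61 and 0.71 for Gm13051, and 1.22, 1.52 and 0.51 for Zfp600, where the last value has adjusted p = 0.1001. They were picked for their values, so the adjusted p between days of 9.24e-05 to 0.000163 overstates the case. No test of a cause was made.

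H19 was lower at the 6 days, and a switch of the H19 and Igf2 domain would raise Igf2, its reciprocally imprinted neighbour. Igf2 was not higher: its log2 fold change was -2.15 at day 5 (adjusted p = 1.36e-05), -0.42 at day 8 (0.262), -0.63 at day 10 (0.0171) and -0.2925 at day 12 (0.232), the highest of the last 3 days. Days 8 and 12 did not pass the threshold, and a rise is not seen at these days. Both genes mark mesoderm and endoderm, so fewer of these cells might lower both and hide a rise of Igf2. The test therefore cannot decide on a switch. Fewer such cells would leave the difference of H19 at day 0 (-1.75, adjusted p = 0.00145) open.

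Splits of a day's libraries that ignore genotype gave few genes in the tests of single days. Every split but the real one mixes the genotypes, so a true difference widens the spread within its groups and holds the count down. The counts of other splits are therefore no rate of false calls. Splits drawn within days share this limit at the days where they mix the genotypes. At each day, 1 of the 10 ways to split 6 libraries into 3 and 3 gave as many genes as the genotypes, the real one, and the highest other counts were 1, 26, 1, 1, 1 and 0 genes at days 0, 3, 5, 8, 10 and 12, against 1770, 210, 1293, 417, 2609 and 878. With 10 splits a share under 0.05 cannot be reached. For the 3 genes of all 6 days, 1 of 100 drawn splits, the real one, reached that count. For the 2229 genes differing between days it was 2 of 100, the second being a draw with 2319 genes that kept the true grouping at 2 days; the highest count after that was 771.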
